A study of Mus musculus with 12 samples.

How the data were processed

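RNA from the testes of ICR mice, an outbred stock, was sequenced in 12 libraries that fall into 4 groups of 3. The deposited description speaks of cultured testis but names no culture step, so it is not known whether the tissue was cultured. The group and the replicate number of each library were taken from the sample labels. The deposited table gives the authors' FPKM values (fragments scaled by transcript length and by the mapped total of the library), per the file headers, with 2 decimals and 1 column per library. The aligner, the counting program, the genome build, the annotation and any filter on genes are not given in the sources used here. FPKM divides by transcript length and by the total of each library, so a fall in a very abundant class of transcripts raises the FPKM of all others.

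The table holds 22221 rows for 12 libraries, and all of its columns were used. Of these rows, 20288 carry a numeric NCBI Gene ID and 1933 are named by the authors as new genes. Symbols were attached through the Gene IDs in a RefSeq gene table (assembly GRCm38.p6), which was used for names and for which genes are neighbours. It matched 20141 IDs and left 147 unmatched. In 423 rows all 12 values are 0, and 716 rows have the same 12 values as another row. The sum of FPKM ranged from 569055 to 576093 in the untreated libraries and from 476127 to 519355 in the busulfan libraries. The table holds no counts, so the depth behind each value is unknown and no counting interval can be given. Low values were searched for steps of 1 read. The most frequent ratio between libraries was shared by at most 5 genes, which is too few to give relative depths.

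Values were analysed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were kept, which left 15472. Fold changes are on this log2(value + pseudocount) scale and understate the change of genes with low values. All 12 libraries were fitted together with 1 mean per group in limma 3.58.1 (R 4.3.3), with a variance trend. The 6 differences between groups were tested with Benjamini-Hochberg adjustment over all genes, and an adjusted p under 0.05 counts as changed. Errors of fold changes are limma's moderated standard errors (SE), and errors of levels are SDs over n = 3 libraries. The labels do not say whether the libraries of a group come from separate animals, so the p-values measure only the spread between these samples, which may be technical.

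A total of 25 gene lists with 533 members was fixed before the data were examined. They cover germ cell stages, somatic cells of the testis, cells of neighbouring tissue and pathways. Of the members, 512 are in the table, 2 of them by an older symbol. No mitochondrially encoded member is among the rows used here, so 24 lists were tested. Each list was tested against all other genes with camera, at a preset correlation of 0.01 and again with the correlation estimated from all 12 libraries. It was also tested with fry, which asks whether its members move on balance in 1 direction. Counts of members are given over all genes and adjusted over the list alone.

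Genes are named by a rule fixed before the data were examined. It takes the 6 largest rises and 6 largest falls per comparison among changed genes with at least 5 FPKM in the higher group and no overlap between libraries, leaving out predicted symbols. With 3 libraries against 3, chance alone gives no overlap in 10% of genes. The rule adds up to 3 members with the smallest p, and the member with the highest level, of each list described. Where fewer than 5 genes passed, it takes the 5 smallest p in each direction as values that did not pass. The rule names 492 pairs of gene and comparison. The text prints 141 of them, a selection made by hand after the values were seen, and the 351 others changed direction more often under the alternatives. Genes outside the rule are marked as chosen after their values were seen.

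The procedure was tested on simulated data with 200 changed genes, using the spread of all libraries and the spread without IMA10 replicate 3. For Sa minus Con, a simulated log2 change of 1 was found in 25% of genes with the first spread and in 71% with the second. For IMA10 minus Sa the shares were 30% and 76%. A simulated log2 change of 2 was found in 65% and 90% of genes for Sa minus Con, and in 56% and 95% for IMA10 minus Sa. Per-library list levels were compared by exact two-sided permutation, which cannot go below p = 0.1 with 3 against 3.

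The alternatives fixed before the data were examined were median-of-ratios scaling, quantile normalization and a pseudocount of 0.1. Others were no filter, a filter of 5 FPKM, fits of only the groups compared, the replicate number as a block, array weights and leaving out each library in turn. Array weights were estimated gene by gene, because limma's default estimate did not converge on these data. Correlations of fold changes between comparisons that share libraries were set beside values from 50 simulations of unchanged groups. Copies of genes were searched with BLAST 2.17.0 among GENCODE M21 transcripts. Further computing and plotting used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.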

Results

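Gene expression was measured by RNA sequencing in testes of ICR mice. The deposited description speaks of RNA from cultured testis but names no culture step, so it is not known whether the tissue was cultured. The untreated group (Con) has 3 libraries. The mice of the other 3 groups received 1 dose of busulfan, an alkylating drug that kills dividing germ cells, at 3 weeks of age. Of these, the Sa group then received saline. The IMC group received gut microbiota from donors given water, and the IMA10 group received gut microbiota from donors given alginate oligosaccharide at 10 mg/kg. The microbiota was given for 2 weeks and testes were collected after another 3 weeks. The labels do not give the age of the untreated mice, and the untreated columns of the table carry another name prefix than the busulfan columns, so a batch cannot be told apart from the untreated group. Values are the authors' FPKM, and read depth is unknown. The number of genes with at least 1 FPKM ranged from 12726 to 14474 per library.

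The libraries were not equally alike within groups. On the first principal component, which held 88.6% of the variance of log2 values, the untreated libraries lay between -167.4 and -161.2. IMA10 replicate 3 lay at -81.1 and the other busulfan libraries between 24.2 and 127.6. IMA10 replicate 3 correlated across genes with the untreated libraries at 0.92 to 0.93, but with IMA10 replicates 1 and 2 at 0.61 and 0.71. Because all libraries share 1 estimate of the spread, this library widens the error of every comparison.

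**Figure D1:**
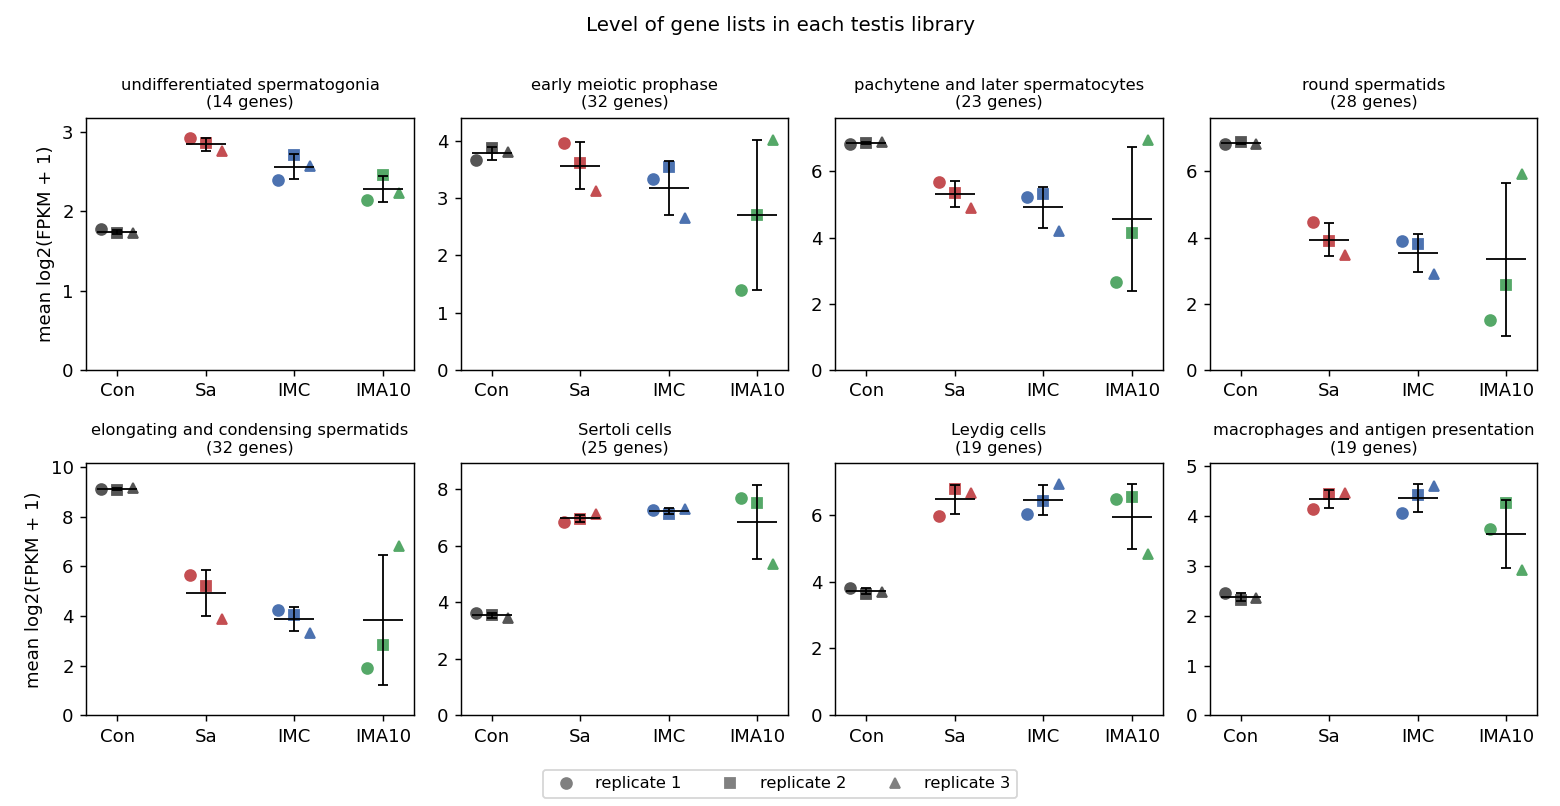
Mean log2(FPKM + 1) of 8 gene lists (y axis) in each of the 12 libraries by group (x axis); points are libraries, bars are the group mean and SD (n = 3). Elongating spermatid genes lie between 9.09 and 9.14 in Con, and at 6.80 in IMA10 replicate 3 against 1.90 and 2.83 in the other IMA10 libraries.

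The comparison of Sa with Con asks what busulfan changed in the testis. Transcripts of late germ cells were far lower after busulfan, and those of somatic cells were higher. Prm1 (Gene ID 19118) and Prm2 (19119), the protamines that package sperm DNA, averaged 10641 ± 363 and 12867 ± 116 FPKM in Con (SD, n = 3) and 293 ± 237 and 348 ± 280 in Sa. Their log2 fold changes were -5.95 ± 1.68 and -5.89 ± 1.63 (SE, limma adjusted p = 0.0094 and 0.0083). The transition proteins Tnp1 and Tnp2, which precede protamines on chromatin, changed by -5.60 ± 1.51 and -5.39 ± 1.5. Spem1, needed for shaping sperm, fell by 5.65 ± 1.20, and the spermatid protein gene Cabs1 fell by 5.46 ± 1.12.

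The fall was graded by germ cell stage. Of the 32 elongating and condensing spermatid genes 30 fell and none rose, with a median log2 change of -4.25 and a camera adjusted p = 2.98e-12. Adjusted over the list alone, 31 fell. Of the 28 round spermatid genes 20 fell (22 adjusted over the list alone), with a median of -2.94. Tssk6, a spermatid kinase, fell by 5.01 ± 0.89, and Gsg1 fell by 4.65 ± 1.10. In the elongating list Klhl10, part of a spermatid ubiquitin ligase, fell by 3.13 ± 0.52. The pachytene and later spermatocyte list had a median of -1.62, with 3 of 23 members past the threshold and 0 adjusted over the list alone. Pgk2, a germ cell glycolytic enzyme, fell by 3.51 ± 1.01. Meig1 was at -2.44 ± 0.91, with an adjusted p = 0.0346 that reached 0.176 among the alternatives. Ldhc, a germ cell lactate dehydrogenase, was at -2.05 ± 1.07 and did not pass (adjusted p = 0.106). In the sperm axoneme list 11 of 30 fell (1 adjusted over the list alone), among them the dynein gene Dnah3 by 2.61 ± 0.61. The counts of these middle stages moved with single libraries and with scaling. Leaving out IMA10 replicate 3, 19 pachytene and 30 axoneme genes fell, over all genes and adjusted over the list alone alike. Without Sa replicate 3 the count over all genes was 1 in both lists, and the pachytene count was also 1 without Con replicate 2 or 3. With median-of-ratios scaling 17 pachytene and 29 axoneme genes fell, and with quantile normalization 6 and 13. With an estimated correlation none of the 4 list calls held (adjusted p = 0.57 with an estimated correlation in each).

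Early germ cell genes moved otherwise. Of the 14 undifferentiated spermatogonia genes 10 rose and 1 fell, the same numbers as when adjusted over the list alone. The camera adjusted p was 0.13 (0.57 with an estimated correlation). By fry it was 0.0001, but fry does not set the list against other genes, and 8052 of all 15472 genes rose. Relative to Sertoli genes the list fell, from between -1.86 and -1.72 in Con to between -4.34 and -3.92 in Sa (mean log2 difference). This measure was not among those fixed before the data were examined. The pseudocount understates the rise of low values, so the size of the fall may be overstated. As a median percent of the Con mean, the list stood at 294 to 440% in Sa and the Sertoli list at 1171 to 1494%. Zbtb16, a stem cell transcription factor, rose from 0.54 ± 0.05 to 3.12 ± 0.39 FPKM. Uchl1 rose by 2.33 ± 0.25 and Foxo1 by 2.23 ± 0.27, while Lhx1, the member that fell and was chosen after its value was seen, had an adjusted p = 0.000353. Of the 15 differentiating spermatogonia genes 10 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.16, and 0.65 with an estimated correlation). Without Sa replicate 1, 6 of them rose over all genes. Adjusted over the list alone 4 rose without Sa replicate 1 or Con replicate 3. Dmrt1 and Kit rose by 2.51 ± 0.32 and 2.37 ± 0.30. Dmrtb1 was at -2.17 ± 1.10 and did not pass. Bulk levels do not show which cells made these transcripts, so rises in either spermatogonial list need not come from spermatogonia. Relative to Sertoli genes the differentiating list also fell, from between -0.94 and -0.73 in Con to between -3.68 and -2.73 in Sa. Of the 32 genes of early meiotic prophase 4 rose, with Prdm9, which sets recombination sites, at 1.10 ± 0.23 (adjusted p = 0.056 with quantile normalization). In the same list 2 fell, Syce2 by 2.01 ± 0.57 and Rec8, chosen after its value was seen, by 1.87. The falls numbered 6 without IMA10 replicate 3, and 1 without Con replicate 1 or Sa replicate 2 or 3. Adjusted over the list alone 1 gene rose and 0 fell, and 4 rose and 5 fell without IMA10 replicate 3. In the piRNA list Fkbp6 rose by 1.69 ± 0.17. Tdrd7 was at -1.54 ± 0.61, with an adjusted p = 0.0427 that reached 0.108 among the alternatives. Leaving out IMA10 replicate 3, 9 piRNA genes fell, and the camera call of this list (adjusted p = 0.0203) had an adjusted p = 0.62 with an estimated correlation.

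**Figure D2:**
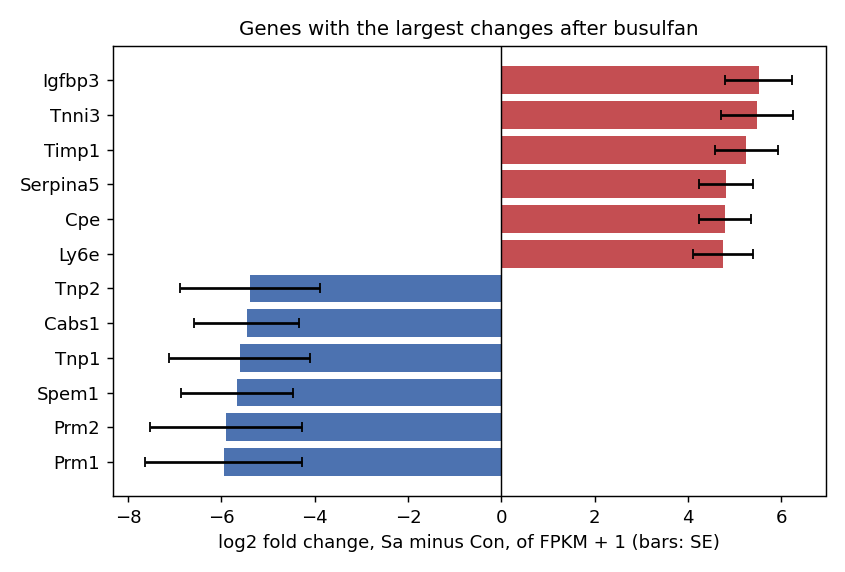
Log2 fold change of FPKM + 1 in Sa minus Con (x axis) for the 6 genes with the largest rise and the 6 with the largest fall (y axis), with SE bars from limma, n = 3 per group. Igfbp3 has the largest rise at 5.52 and Prm1 the largest fall at -5.95.

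Somatic transcripts rose in every list of testis cells. The largest rises were in Igfbp3, which binds insulin-like growth factors (1.3 ± 0.33 to 104 ± 10 FPKM, log2 fold change 5.52 ± 0.71), and in Tnni3, a troponin (5.47 ± 0.78). Timp1, a metalloproteinase inhibitor, rose by 5.24 ± 0.68, Serpina5 by 4.81 ± 0.58, Cpe by 4.79 ± 0.55 and Ly6e by 4.75 ± 0.64. All 25 Sertoli cell genes rose, with a median of 3.47. Clu went from 352 ± 30.5 to 6101 ± 708 FPKM, Inha, an inhibin subunit, rose by 4.41 ± 0.55, and Amh, the anti-Müllerian hormone, by 3.64 ± 0.44. Of the 19 Leydig cell genes 18 rose, with a median of 3.09. The Leydig hormone gene Insl3 went from 463 ± 12.6 to 4942 ± 1550 FPKM, and Hsd17b3, the last enzyme of testosterone synthesis, rose by 3.71 ± 0.53. Among macrophage and antigen presentation genes 17 of 19 rose (median 2.59), with Lyz2 at 3.22 ± 0.45 and C1qc at 3.13 ± 0.41. Aif1 of that list fell from 320 ± 17 to 20.1 ± 9.0 FPKM. Of the 14 peritubular myoid genes 12 rose (median 2.29), among them Acta2 by 2.95 ± 0.35, and Actg2 fell from 251 ± 8 to 27.5 ± 5.7 FPKM. All 14 endothelial genes rose (median 2.06), with Cdh5 at 2.36 ± 0.36. In each of these 5 lists the counts adjusted over the list alone were the same. Camera gave adjusted p-values of 2.09e-05 for Sertoli, 0.00117 for Leydig, 0.0132 for macrophage, 0.0203 for myoid and 0.00857 for endothelial genes. None held with the estimate (adjusted p = 0.57 with an estimated correlation). That estimate included IMA10 replicate 3 and was not repeated without it, so how far this library caused the lost calls is not known.

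Most pathway lists rose with the somatic lists, but the retinoic acid and mitotic lists did not pass camera. Junction genes of the blood-testis barrier rose in 19 of 22 cases and fell in 3 (1 without any of Con replicates 1 to 3 or Sa replicate 1 or 3), with Cldn11 at 3.98 ± 0.54 and Gja1 at 3.90 ± 0.51. Cholesterol synthesis genes rose in 16 of 22 cases (17 adjusted over the list alone), with Msmo1 at 3.67 ± 0.47. Of the p53 and apoptosis list 19 of 24 rose, Bax by 2.38 ± 0.33 and Sesn2 by 3.05 ± 0.48. Of the inflammation list 15 of 17 rose, with Nfkbia at 3.76 ± 0.54. The p53 and inflammation medians, 1.55 and 1.74, lay below those of the 5 testis cell lists, and 8052 of all 15472 genes rose. Antioxidant genes rose in 18 of 25 cases, with Gstm1 at 3.49 ± 0.49, while Gpx4, abundant in spermatids and chosen after its value was seen, fell by 1.93. Extracellular matrix genes rose in 21 of 22 cases, with Sparc at 3.64 ± 0.54. For the last 4 lists the rises adjusted over the list alone numbered the same. Camera adjusted p-values of these 6 lists lay between 0.000359 and 0.0243. With an estimated correlation the adjusted p was 0.62 for the inflammation list and 0.57 for the others. Retinoic acid genes rose in 11 of 15 cases (Cyp26b1 by 2.37 ± 0.33; camera adjusted p = 0.11). Mitotic genes rose in 9 of 23 cases and none fell (camera adjusted p = 0.82), with Mcm3 at 1.79 ± 0.19. With IMA10 replicate 3 left out, 5 mitotic genes fell. Markers of other tissue were mixed. Of 6 red blood cell genes 4 rose, with Hba-a1 at 2.76 ± 0.45. Of 6 adipocyte genes 3 rose and 3 fell, with Adipoq at -2.61 ± 0.45, and without Con replicate 1 or 2 or Sa replicate 3 the falls numbered 1. Of 3 epididymis genes 1 fell, and 2 without IMA10 replicate 1 or 3 and with either scaling. For these last 5 lists the counts adjusted over the list alone were the same.

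In all, 11015 of 15472 genes changed between Sa and Con, 8052 upward and 2963 downward, with a median log2 change of 0.60 over all genes. Median-of-ratios scaling moved that median by -0.63, and then 5847 genes rose and 6069 fell. Quantile normalization moved it by -0.41 and gave 5699 up and 4514 down. Relative to the all-gene median, the Sertoli list stood 2.87 higher and the elongating list 4.86 lower, on the log2 scale. With median-of-ratios scaling 8 undifferentiated spermatogonia genes rose and 3 fell, and in the differentiating list 4 rose and 1 fell. The counts for early meiotic prophase became 1 and 8, and for the mitotic list 4 and 4. The falls in the piRNA list went from 1 to 8, in the round list from 20 to 28, in the elongating list from 30 to 32 and in the antioxidant list from 2 to 6.

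The comparison of IMC with Sa asks what microbiota from water-fed donors did after busulfan. No gene passed in limma: 0 of 15472 at adjusted p under 0.05, and 134 at unadjusted p under 0.05, where 773.6 are expected by chance. Of the genes with the smallest p, Fggy averaged 15.9 ± 1.6 FPKM in IMC and 4.50 ± 2.64 in Sa (unadjusted p = 0.0055), and the myeloid receptor Trem2 averaged 11.3 ± 3.3 against 5.13 ± 1.98. Oscar, the metallothionein Mt2 and the mitochondrial ATPase inhibitor Atpif1 were also higher, by 0.42 ± 0.16, 0.43 ± 0.17 and 0.35 ± 0.14 (log2 ± SE). Paox, an enzyme of polyamine breakdown, was lower by a log2 difference of -0.70 ± 0.18, the cell cycle gene Ccnd1 by -0.53 ± 0.17, Map7d1 by -0.48 ± 0.15, Ptp4a3 by -0.52 ± 0.17 and Ccdc57 by -0.61 ± 0.20. None of these passed (adjusted p = 1 for each).

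As lists, 9 of 24 passed camera in IMC minus Sa, all with 0 members past the threshold, over all genes and adjusted over the list alone. Germ cell lists lay lower. The elongating list had a median of -0.75 and all 32 members lower (adjusted p = 6.07e-06), with Prm2 at 30.6 ± 14.3 FPKM in IMC against 348 ± 280 in Sa. The undifferentiated spermatogonia list had a median of -0.37 with 12 of 14 lower, Zbtb16 at 1.79 ± 0.42 against 3.12 ± 0.39 FPKM. With a filter of 5 FPKM fewer of its members were tested, and its camera direction turned upward at a median of -0.02. The differentiating list, with Sohlh2 at -0.88 ± 0.47, had all 15 members lower. So had early meiotic prophase in all 32, with Rec114 at -0.58 ± 0.33. The piRNA (median -0.51), mitotic (-0.33) and cholesterol (-0.18) lists also passed downward. These medians were nearest to 0 without Sa replicate 1 (-0.28), IMC replicate 3 (-0.11) and Sa replicate 2 (-0.05). The differentiating and early meiotic medians, -0.41 in both, were -0.19 and -0.18 without IMC replicate 3. The first reached -0.68 without IMC replicate 2 and the other -0.64 without Sa replicate 3. The elongating median was -0.48 without Sa replicate 1 and -1.22 without Sa replicate 3. The mitotic median reached -0.57 without IMC replicate 2, and the cholesterol median -0.34 without IMC replicate 3. The pachytene and round spermatid lists did not pass (adjusted p = 0.18 in both), with Tex101 at -0.70 ± 0.73 and Tssk6 at -1.79 ± 0.89. Upward, the Sertoli list passed with all 25 members higher and a median of 0.26 (Rhox8 at 0.78 ± 0.49), as did the inflammation list with a median of 0.18, which was -0.02 without IMC replicate 3. The Leydig and macrophage lists did not pass (adjusted p = 0.45 and 0.19), and Lyz2 was at 0.24 ± 0.45. No list held with an estimated correlation: adjusted p = 0.25 with an estimated correlation for undifferentiated spermatogonia and 0.82 for the other 8. When the levels per library were compared, 3 of 24 lists had no overlap between the groups (undifferentiated spermatogonia, Sertoli and adipocyte; exact p = 0.1, the smallest possible). The elongating list overlapped (exact p = 0.3). Without IMC replicate 1, 13 lists passed, and without IMC replicate 3 the number was 7. Without IMA10 replicate 3, 13 lists passed and 2 undifferentiated spermatogonia genes were lower adjusted over the list alone.

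The comparison of IMA10 with Sa asks what microbiota from oligosaccharide-treated donors did after busulfan. Again 0 of 15472 genes passed in limma, with 928 at unadjusted p under 0.05, of which 891 were lower and 37 higher. In the undifferentiated spermatogonia list 6 of 14 genes were lower when adjusted over the list alone, and 0 over all genes (8 in both counts without IMA10 replicate 3). Ret, the receptor of the stem cell factor GDNF, averaged 0.69 ± 0.26 FPKM against 1.86 ± 0.24 in Sa, Zbtb16 1.34 ± 0.35 against 3.12 ± 0.39, and Bcl6b 1.92 ± 0.17 against 3.26 ± 0.14. The list passed camera (median -0.55, adjusted p = 3.2e-08) and fry (adjusted p = 0.0057), and had an adjusted p = 0.11 with an estimated correlation. In the differentiating spermatogonia list 10 of 15 were lower adjusted over the list alone and 0 over all genes (11 over all genes without IMA10 replicate 3). Kit averaged 6.98 ± 0.99 against 19.1 ± 7.1 FPKM and Stra8 11.2 ± 6.6 against 30.2 ± 9.3. This list passed camera (median -1.09, and -0.61 without IMA10 replicate 1; adjusted p = 4.37e-09), with an adjusted p = 0.40 with an estimated correlation. Without Sa replicate 2 or IMA10 replicate 1, the count adjusted over its list alone was 0. Levels per library in both lists had no overlap between IMA10 and Sa (exact p = 0.1, the smallest possible), as in 4 of 24 lists in all, with the adipocyte and retinoic acid lists. The differentiating levels (mean log2) nearly met, at 3.38 in IMA10 replicate 3 and 3.42 in Sa replicate 3. Relative to Sertoli genes, IMA10 replicate 3 lay above every Sa library in both lists (-3.12 and -1.96 against at most -3.92 and -2.73). IMA10 replicates 1 and 2 lay below every Sa library in both.

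The counts of IMA10 minus Sa in all genes and in further lists also depended on how 1 library was treated. Without IMA10 replicate 3, 4931 genes passed, and with array weights 5415. Without that library 31 of 32 elongating, 28 of 28 round, 21 of 23 pachytene and 25 of 32 early meiotic genes were lower and 21 of 25 Sertoli genes were higher, each past the threshold over all genes. With all libraries none of these passed. Prm2 was 5.72, 7.84 and 817 FPKM in IMA10 replicates 1, 2 and 3, against 587, 418 and 40.1 in Sa. The elongating and round lists had camera adjusted p = 0.16 and 0.96, the pachytene list 0.43, the Sertoli list 0.07 and the Leydig list 0.12. Gsg1 was at -1.22 ± 1.10, Tex101 at -1.26 ± 0.73, Cyp17a1 at -0.96 ± 0.51 and the Sertoli gene Trf at -0.56 ± 0.46. Trf was higher in IMA10 than in Sa without that library. The early meiotic list passed camera downward (median -0.86, Rec114 at -1.32 ± 0.33, adjusted p = 0.66 with an estimated correlation). Its median was -0.17 without IMA10 replicate 1 and -1.62 without replicate 3.

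Somatic and cycling lists also passed camera downward in IMA10 minus Sa. These were macrophage (median -0.76, Csf1r at -0.96 ± 0.37), endothelial (-0.65, Vwf at -0.89 ± 0.27), extracellular matrix (-0.55, Fn1 at -1.08 ± 0.25), mitotic (-0.82, Mcm2 at -0.94 ± 0.23), myoid (-0.50), cholesterol (-0.43) and piRNA (all 19 members lower) lists. The medians were -0.31, -0.18, -0.22 and -0.15 for macrophage, endothelial, matrix and myoid genes and -0.24 for cholesterol genes when IMA10 replicate 3 was left out. When IMA10 replicate 1 was left out, the mitotic median was -0.13 and the piRNA median 0.06. They were -1.31 and -2.02 without replicate 3, and the matrix median was -0.83 without replicate 1. Levels per library overlapped between the groups in all 7 lists (exact p of 0.2 to 0.5). Their calls were lost, with adjusted p = 0.66 with an estimated correlation for all but the piRNA list, which had 0.91. In all 7 lists 0 members passed over all genes. Adjusted over the list alone, 1 matrix and 1 mitotic gene was lower and 0 in the others. Without IMA10 replicate 2 the counts over the list alone were 14 for macrophage and 12 for matrix genes, and without IMA10 replicate 3 the mitotic count was 19 and the piRNA count 19. Single genes with the smallest p, none of which passed, were Ski (6.82 ± 0.79 against 13.2 ± 0.2 FPKM, adjusted p = 0.62), Ccnd1 at -0.94 ± 0.17, Map7d1 at -0.74 ± 0.15, Nucb1 at -0.80 ± 0.16 and Tsc22d3 at -1.05 ± 0.22. Higher were Atpif1 at 0.52 ± 0.14, the spermidine synthase gene Srm at 0.85 ± 0.26, and the metallothioneins Mt1 at 0.59 ± 0.19 and Mt2 at 0.51 ± 0.17. Hbb-bs was listed at 15.3, 29.2 and 2.84 FPKM in IMA10 and at 0.23, 0.23 and 0 in Sa. The red blood cell list that holds it had a median of -0.35 (0.31 without IMA10 replicate 3). Its levels per library overlapped between the groups (exact permutation p = 0.5), so Hbb-bs alone does not show a rise of that list. Median-of-ratios scaling moved the all-gene median, -0.19, by 0.18, and the spermatogonial medians stayed below 0 at -0.36 and -0.88. It moved that of the Sertoli list from -0.15 to 0.07.

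The comparison of IMA10 with IMC asks whether treating the donor with the oligosaccharide mattered. The sample labels used here name no donor for each library, so the p-values need not measure the spread between donors. In limma 0 of 15472 genes passed and 328 had an unadjusted p under 0.05. Without IMA10 replicate 3 there were 2, without Sa replicate 3 there was 1, and with array weights there were 1118. The genes with the smallest p, all with adjusted p = 1.0, were lower Rsph3b, a radial spoke gene (16.6 ± 4.7 against 57.6 ± 24.6 FPKM), Tagap at -1.21 ± 0.34, the leukocyte gene Lsp1 at -1.05 ± 0.33, Serhl at -0.71 ± 0.22 and Ptprf at -0.81 ± 0.25. Higher were Amotl1 at 0.45 ± 0.15, Zfp972 at 0.48 ± 0.16, Dtx3 at 0.68 ± 0.23, the claudin Cldn3 at 0.91 ± 0.34 and Rnpep at 0.44 ± 0.17.

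In IMA10 minus IMC, 14 of 24 lists passed camera with 0 members past the threshold, over all genes and adjusted over the list alone. The macrophage list had a median of -0.82 and all 19 members lower (adjusted p = 9.52e-08, and 0.60 with an estimated correlation), with Csf1r at -0.96 ± 0.37 and H2-Aa at -1.29 ± 0.51. Its levels per library overlapped between the groups (exact p = 0.2). Of the 24 lists 1 had no overlap, that of retinoic acid (exact p = 0.1, the smallest possible). Without IMA10 replicate 2, 14 macrophage genes were lower adjusted over the list alone. Extracellular matrix genes had a median of -0.50 (Col1a1 at -0.67 ± 0.27; adjusted p = 0.66 with an estimated correlation). The differentiating and undifferentiated spermatogonia lists had medians of -0.58 and -0.34, with Kit at -0.90 ± 0.30 and Ret at -0.38 ± 0.14 (adjusted p = 0.60 with an estimated correlation in both). Early meiotic genes had a median of -0.51, with M1ap at -1.23 ± 0.49, and the mitotic list a median of -0.47. Leydig genes had a median of -0.55 (Hsd17b3 at -0.85 ± 0.53), endothelial -0.42, myoid -0.40, antioxidant -0.43, inflammation -0.43, p53 -0.24 and retinoic acid -0.37. Leaving out IMA10 replicate 3 moved the macrophage and matrix medians to -0.38 and -0.11. It moved those of the Leydig, endothelial, inflammation and p53 lists above 0, to 0.06, 0.02, 0.05 and 0.03, and those of the myoid, antioxidant and retinoic acid lists to -0.01, -0.01 and -0.21. Leaving out IMA10 replicate 1 moved the differentiating and undifferentiated medians to -0.17 and -0.15, and the early meiotic and mitotic medians above 0, to 0.26 and 0.12. Medians also moved further down. Those of the Leydig and endothelial lists were -0.90 and -0.70 without IMA10 replicate 1. The macrophage, inflammation, p53, retinoic acid and myoid medians were -1.24, -0.79, -0.44, -0.68 and -0.61 without IMA10 replicate 2, and the differentiating, early meiotic and mitotic medians -0.90, -1.12 and -1.02 without IMA10 replicate 3. The adjusted p was 0.60 with an estimated correlation for the retinoic acid list and 0.86 for the early meiotic, mitotic and 7 other lists of this group. The elongating list passed upward against other genes (adjusted p = 0.0113, and 0.86 with an estimated correlation), although its median was -0.14. Prm2 was at 0.34 ± 1.63 and Tssk6 at 0.83 ± 0.89, and both were lower in IMA10 without IMA10 replicate 3, Prm2 also without IMC replicate 3. The pachytene and round lists did not pass (adjusted p = 0.80 and 0.20), with Ccna1 at -0.95 ± 1.05. Nor did the Sertoli list (0.10), with Trf at -0.91 ± 0.46. Without IMA10 replicate 3, 21 elongating, 27 round and 21 pachytene genes were lower and 7 Sertoli genes higher, adjusted over the list alone. Without IMC replicate 3, 8 lists passed. Median-of-ratios scaling moved the all-gene median, -0.14, by 0.12.

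Both microbiota groups were also set against Con, to see how far they stood from untreated testis. In IMC 11465 genes changed (7862 up, 3603 down), and in IMA10 11077 changed (7383 up, 3694 down). With median-of-ratios scaling the splits were 6018 up and 6302 down for IMC, and 5620 up and 5817 down for IMA10. That scaling moved the all-gene medians, 0.52 and 0.41, by -0.56 and -0.45. Protamine and transition protein genes had the largest falls in both. Prm2 was at -8.80 ± 1.63 in IMC and -8.46 ± 1.63 in IMA10, Prm1 at -8.41 ± 1.68 and -8.21 ± 1.68, Tnp1 at -7.79 ± 1.51 and -7.64 ± 1.51, and Tnp2 at -7.93 ± 1.5 and -7.53 ± 1.5. Spem1 was at -7.68 ± 1.20 and -7.05 ± 1.20, and the spermatid histone H2al2a at -7.40 ± 1.13 and -6.69 ± 1.13. Among the 6 largest rises, 4 genes stood in both comparisons: Timp1 (6.06 ± 0.68 in IMC, 4.77 ± 0.68 in IMA10), Tnni3 (5.73 ± 0.78 and 5.31 ± 0.78), Igfbp3 (5.62 ± 0.71 and 4.84 ± 0.71) and Cpe (5.06 ± 0.55 and 4.58 ± 0.55). Ly6e at 5.23 ± 0.64 and the water channel Aqp5 at 5.09 ± 0.63 were the others in IMC.

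In IMA10 minus Con the list of largest rises also held Tubb5, a tubulin, at 5.03 ± 1.71 and the collagen receptor Ddr1 at 4.48 ± 1.00. Both varied within groups. Tubb5 lies in the chromosome 17 window described below, whose genes differed between untreated libraries. It was 0.18, 30.3 and 95.5 FPKM in Sa, so its rise in IMA10 cannot be told apart from that pattern. Tubb5 was 0.05, 8.04 and 0.19 FPKM in Con, and it did not pass without Con replicate 1 or 3 or without IMA10 replicate 1 or 2 (adjusted p up to 0.075). Ddr1 was 0.12 and 1.00 FPKM in Con replicates 1 and 2 and was listed at 0 in replicate 3.

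By list, 31 of 32 elongating spermatid genes fell in IMC and 32 in IMA10, against Con. Of the 28 round spermatid genes 22 and 28 fell. Adjusted over the list alone these counts were 32 and 32, and 23 and 28. All 25 Sertoli genes rose in both groups, with medians of 3.70 and 3.24, and 18 of 19 Leydig genes rose in both. Macrophage genes rose in 17 and 15 of 19 cases. The Sertoli, Leydig and macrophage counts were the same adjusted over the list alone. Undifferentiated spermatogonia genes rose in 7 and 5 of 14 cases and fell in 2, also adjusted over the list alone. Differentiating genes rose in 5 and 4 of 15 cases, and in 4 and 4 adjusted over the list alone. The rises in IMC numbered 8 over all genes without IMA10 replicate 1. In IMA10 1 differentiating gene fell, 3 without IMA10 replicate 3 and 0 without any 1 Con library or IMA10 replicate 1 or 2. Median-of-ratios scaling gave 2 rises and 2 falls of differentiating genes in IMA10 and moved their median from 0.04 to -0.30. The undifferentiated median in IMA10 went from 0.27 to -0.15. Unscaled and with 1 library left out, these medians ranged from -0.23 to 0.61 and from 0.18 to 0.45. In IMC median-of-ratios scaling gave medians of 0.16 and 0.14 for the undifferentiated and differentiating lists, against 0.55 and 0.68 without it. Neither spermatogonial list passed camera (adjusted p = 0.43 and 0.45 in IMC, 0.71 and 0.78 in IMA10). Of the 23 pachytene genes 8 fell in IMC and 16 in IMA10 (0 and 17 adjusted over the list alone). Without IMA10 replicate 3 these counts were 21 and 22, without IMC replicate 3 the first was 1, and without IMA10 replicate 1 or 2 the second was 1 (0 adjusted over the list alone, also without any 1 Con library). Of the 32 early meiotic genes 3 and 9 fell, and 12 and 25 without IMA10 replicate 3. The 9 became 3 when any 1 Con library or IMA10 replicate 1 or 2 was left out. With median-of-ratios scaling the pachytene falls were 21 in both groups and the early meiotic ones 13 and 17. Adjusted over the list alone 1 and 3 fell, and 10 and 25 without that library. IMA10 replicate 3 itself was not below Con. Its pachytene and early meiotic levels (mean log2) were 6.94 and 4.01, against at most 6.88 and 3.88 in Con. Levels per library of both lists overlapped between IMA10 and Con (exact permutation p = 0.4 in both). In all 17 lists passed camera in each comparison and none with an estimate, where the pachytene, round, elongating, Sertoli, Leydig and macrophage lists had adjusted p = 0.60 with an estimated correlation in IMC and 0.54 in IMA10.

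The last question was whether the difference between IMA10 and IMC runs against the change that busulfan made. Across 15472 genes, which are not independent replicates, the fold changes of IMA10 minus IMC and of Sa minus Con had a Pearson correlation of -0.50 and a Spearman correlation of -0.59. Of the 11015 genes changed in Sa minus Con, 84.4% had the opposite sign in IMA10 minus IMC. The share was also 74.8% for IMA10 minus Sa, whose correlation was -0.02. An all-gene median below 0 (-0.14 in IMA10 minus IMC) raises such a share, since most busulfan changes were upward. IMA10 minus IMC and Sa minus Con share no library, and their covariance was -0.255. Simulations without effects gave -0.0007, but they drew each gene independently, so a value this small was fixed in advance. They do not show how far real libraries that vary jointly can move the covariance. The correlation of -0.50 rested on IMA10 replicate 3, without which it was 0.66, and it was -0.16 without IMC replicate 3. It was -0.85 without IMA10 replicate 1 and -0.77 without IMA10 replicate 2. Against IMA10 minus Sa and IMC minus Sa, which share the Sa libraries with the first comparison, the correlations were -0.02 and 0.52, with covariances of -0.0107 and 0.245. The first was -0.73 without IMA10 replicate 1, -0.53 without IMA10 replicate 2, -0.30 without Sa replicate 1, 0.18 without Sa replicate 3 and 0.72 without IMA10 replicate 3. The second was 0.21 without Sa replicate 1 and 0.18 without IMC replicate 3. Unchanged groups gave -0.13 for both correlations and a covariance of -0.106 and -0.105, so sharing the Sa libraries lowers both values. The simulated Sa libraries took the spread pooled over all 12 libraries, which IMA10 replicate 3 widens. Elongating list levels had an SD of 2.60 in IMA10 against 0.92 in Sa. How far sharing lowers the values may therefore be overstated. The 3 Sa libraries cannot be divided between these comparisons with at least 2 libraries for each.

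**Figure D3:**
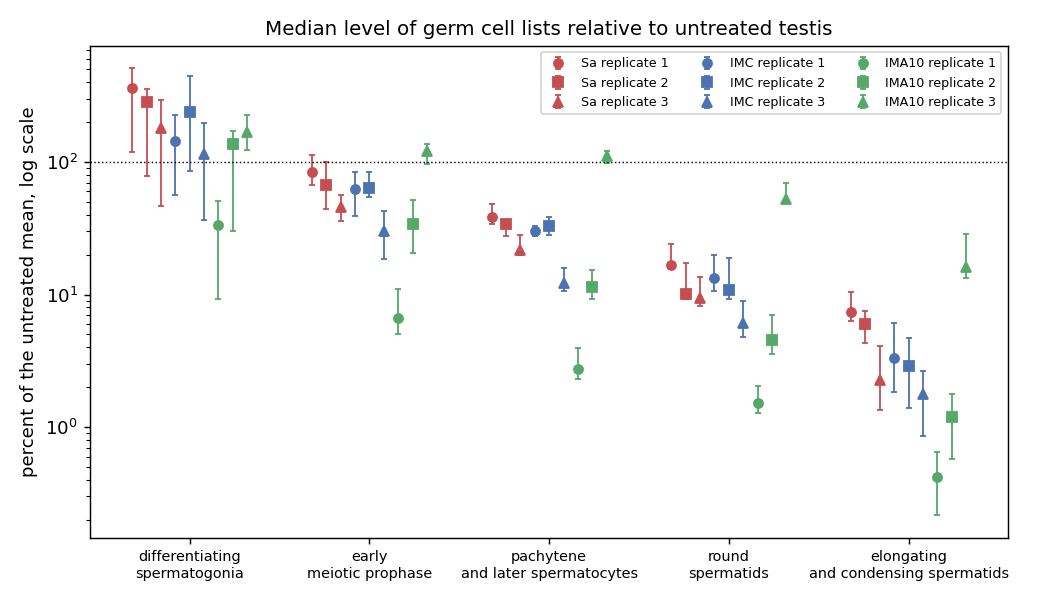
Median level of 5 germ cell lists as a percent of the untreated mean (y axis, log scale) in each of the 9 busulfan libraries, for list members with at least 5 FPKM in Con (x axis, lists in order of germ cell development); bars are 95% bootstrap intervals over genes. IMA10 replicate 3 reads 111.6% for the pachytene list and 16.3% for elongating spermatids.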

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

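The alternatives were fixed before the data were examined, and the names printed here were picked by hand from the genes the naming rule allows, after their values were seen. That choice matters for stability: 6 of the 141 printed pairs of gene and comparison changed sign under at least 1 alternative, against 47 of the 351 that were not printed. In IMA10 minus IMC the numbers were 4 of 21 and 25 of 55, and in IMA10 minus Sa 1 of 25 and 13 of 43. Calls were lost under at least 1 alternative for 4 printed and 29 unprinted pairs, and gained for 29 printed and 47 unprinted ones. Of the 25 printed pairs of IMA10 minus Sa, which the report gives as not passing, 22 gained a call. No printed or unprinted gene changed sign in Sa minus Con or IMC minus Con. Read depth is unknown, so its effect could not be assessed. The cause of the changes below was not tested, except where 1 library was left out or given little weight.

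With quantile normalization 19 lists passed in IMA10 minus Sa. With a pseudocount of 0.1 the count of changed genes was 1 in IMC minus Sa and 1 in IMA10 minus Sa, and the correlation of Sa minus Con with IMA10 minus Sa was 0.0616. Without a filter the counts were 1 and 2. With a filter of 5 FPKM the undifferentiated spermatogonia list in IMC minus Sa turned upward against other genes at a median of -0.019, and that correlation was 0.0477. Fitting only the groups compared gave 7696 genes in IMA10 minus Con. With an estimated inter-gene correlation 0 lists passed in each of the 6 comparisons. This estimate used all 12 libraries and was not repeated without IMA10 replicate 3, so it cannot separate weak lists from the effect of that library.

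Array weights gave IMA10 replicate 3 a weight of 0.0239 and called 5415 genes in IMA10 minus Sa and 1118 in IMA10 minus IMC. Lyz2 was then at -0.0904 in IMC minus Sa and Trf at 0.0823 in IMA10 minus Sa. In IMA10 minus IMC Prm2 was at -1.96, Tssk6 at -0.37 and Hsd17b3 at 0.0274. List medians there were -1.52 for elongating spermatids, 0.18 for Leydig, -0.0169 for myoid, -0.0171 for macrophage, 0.0341 for endothelial, 0.093 for p53, 0.195 for inflammation, 0.0229 for antioxidant and -0.0606 for matrix genes, all with their camera direction turned. The correlation of Sa minus Con was 0.65 with IMA10 minus IMC and 0.67 with IMA10 minus Sa.

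Leaving out 1 library at a time, the count of changed genes ranged from 0 to 4931 in IMA10 minus Sa and from 0 to 2 in IMA10 minus IMC, and 10 to 17 and 8 to 17 lists passed. The correlation of Sa minus Con ranged from -0.85 to 0.66 with IMA10 minus IMC and from -0.73 to 0.72 with IMA10 minus Sa. In IMA10 minus Sa Trf ranged from -0.97 to 0.0531 and the piRNA median from -2.02 to 0.0628. In IMA10 minus IMC Prm2 ranged from -1.91 to 1.56, Tssk6 from -0.37 to 1.45 and Ccna1 from -2.41 to 0.25. List medians there ranged from -1.12 to 0.26 for early meiotic, -1.74 to 0.81 for elongating, -0.90 to 0.057 for Leydig, -0.61 to -0.00796 for myoid, -0.70 to 0.0212 for endothelial, -0.44 to 0.0339 for p53, -0.79 to 0.0534 for inflammation, -0.64 to -0.0128 for antioxidant and -1.02 to 0.12 for mitotic genes.

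With the replicate number as a block 10301, 0, 0, 0, 10552 and 9989 genes changed, in the order Sa minus Con, IMC minus Sa, IMA10 minus Sa, IMA10 minus IMC, IMC minus Con and IMA10 minus Con. The block is balanced over the groups, so it cannot move fold changes or their correlations. The numbers gave no clear sign of pairing: 5 of 18 pairs had a correlation above 0.1, and 1 of 12 libraries correlated best with its own number. Between Sa and IMC the values were 0.31, -0.09 and 0.55 for replicates 1 to 3, and IMA10 with IMC replicate 3 gave -0.765. Libraries that stand apart also set these correlations, so pairing cannot be excluded.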

Other observations

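The tests of the 3 patterns below were all chosen after the results were seen, while the counts over other splits of the libraries were planned.

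Changes after busulfan were counted by chromosome, without a test between chromosomes. In Sa minus Con 411 of 667 X-linked genes rose and 170 fell, with a median log2 change of 1.17. Of 13661 autosomal genes 7273 rose and 2475 fell, with a median of 0.62. Of 73 Y-linked genes 3 rose and 52 fell, with a median of -1.36. The row of Col19a1, a collagen gene chosen after its values were seen, had the highest FPKM in all 9 busulfan libraries, at 5255 to 17346. It ranked 7 to 10 in Con at 2623 to 3061 FPKM. Among GENCODE transcripts 0 other genes matched it, but genomic copies outside these transcripts were not searched. Whether the reads came from this gene is therefore not known. The level of undifferentiated spermatogonia genes relative to Sertoli genes was -1.86 to -1.72 in Con, -4.34 to -3.92 in Sa and -4.86 to -4.40 in IMC. In IMA10 it was -5.55, -5.03 and -3.12 (mean log2 difference, replicates 1 to 3).

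IMA10 replicate 3 stood apart from the other busulfan libraries. A mixture with RNA of a testis like those of Con would bring all germ cell stages at 1 share. The fitted share was instead 96.9 percentage points higher for pachytene than for elongating spermatid genes (95% bootstrap interval 76.8 to 107). A testis with other proportions of germ cell stages was not tested as a source. A swap with an untreated library is argued against by the elongating list of IMA10 replicate 3, 2.29 below the lowest untreated library on the log2 scale. A wrong label within the busulfan groups stays open: the highest elongating level of an Sa or IMC library was 5.65, against 6.80 in IMA10 replicate 3, and a single wrong label needs no partner. The levels fell from the pachytene to the round and elongating lists in all 9 busulfan libraries (38.7, 16.7 and 7.43% in Sa replicate 1), so that order does not set this library apart, and no biological explanation was tested.

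Somatic lists rose by different amounts in Sa. Loss of germ cell RNA would raise every somatic type alike only if germ cells add nothing to the untreated level of its genes. The Sertoli list rose by 1.03 more than the endothelial list (log2, 95% bootstrap interval over genes 0.81 to 1.91), and by 0.86 to 1.23 in each Sa library. These were the highest and lowest of 5 lists fixed before the data were examined, and dealing the 79 members to the lists at random gave a gap as large in 72 of 10000 deals (permutation p = 0.0073). The interval and the deals take genes as independent and do not measure the spread between samples. Part of the untreated level of endothelial members could come from germ cells, which cannot be told apart here: 0 endothelial members reached the Sertoli median, and bulk levels do not show which cells made them. The gap therefore does not decide whether loss of germ cell RNA explains the different rises. No biological explanation was tested.

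Neighbouring genes on chromosome 17 differed between untreated libraries. Of the 83 genes with the largest range within Con, among 8279, 7 lay within 1 Mb, against at most 5 in 1000 random draws. A variant carried by some mice of this outbred stock may place such genes together, which stays open: their median correlation was -0.09 (0.09 for pairs on different chromosomes), but a variant can move neighbours in opposite ways. After that result the window was widened to 4 Mb and the sign of correlations dropped, which gave 17 genes (at most 7 in draws) and a median size of 0.56 against 0.44 (with sign 0.06 against 0.12, and within 1 Mb a size of 0.21 against 0.39). Among GENCODE transcripts 3 of the 17 had a near-identical copy, which argues against reads shared with these transcripts for most of the genes. The authors' annotation is not known, and copies outside these transcripts were not searched, so misplaced reads stay possible. In a block noticed afterwards, Mdc1, Dhx16 and Gnl1 were at 0.84, 0.73 and 2.80 FPKM in Con replicate 1, 16.2, 15.1 and 35.3 in replicate 2, and 1.12, 0.72 and 3.48 in replicate 3.

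The 6 libraries of each comparison have 10 splits with the real one included, too few for a share under 0.05. The count of changed genes was 11015 for Sa minus Con (highest other split 0), 11465 for IMC minus Con (0) and 11077 for IMA10 minus Con (2), each reached by 1 split, the real one. It was 0 for IMC minus Sa (1), IMA10 minus Sa (4183) and IMA10 minus IMC (2667), reached by all 10 splits. The splits calling up to 4183 genes, where the real one calls 0, point to a structure among the samples, in which IMA10 replicate 3 stands apart. Lists passing numbered 16 for Sa minus Con (highest other 17, 5 splits as large), 9 for IMC minus Sa (19, 5), 10 for IMA10 minus Sa (19, 9), 14 for IMA10 minus IMC (18, 8), 17 for IMC minus Con (18, 5) and 17 for IMA10 minus Con (18, 3). The correlation of -0.50 with Sa minus Con was reached in size by all 10 splits of the IMA10 and IMC libraries, with 0.87 the highest other.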
